A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

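Genomic DNA of meiotic yeast cells at 0 h and 5 h in sporulation medium was digested with EcoRI, single-stranded DNA was enriched on BND cellulose, and it was labelled with Cy3 or Cy5 by random priming without denaturation, per the labels' protocols. Each of the 12 arrays held the 5 h sample of a strain in one dye and its 0 h sample in the other, in 6 groups of 2. The 5 h sample was in Cy5 on both dmc1 and both rDNA delete arrays, and in Cy5 on one and Cy3 on the other array of each further group, per the labels.

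The intensity values came from 1 scanner file per array, and the processed signals were background-subtracted and dye-normalized (linear) by Agilent Feature Extraction (version 9.1.3.1 or 10.1.1.1), per the file headers. Version 9.1.3.1 was used for the pch2 dmc1 and sir2 dmc1 arrays only. These arrays had 56 to 872 saturated spots and all others 0. A table of log2 ratios deposited by the authors gave 1 column per array and 1 average per strain. How these were normalized is not given in the sources used here. All 40743 positions of that table matched a probe by chromosome and start. Its columns correlated with their own array's processed log2 ratios at r from 0.709 to 0.944, and with the other replicate's at 0.16 to 0.7, except for sir2 dmc1. The column medians were -0.0011 and 0.017 for dmc1, -0.015 and 0.0023 for pch2 dmc1, -0.01 and 4e-04 for sir2 dmc1, -0.0058 and 1e-04 for orc1-161 dmc1, -7e-04 and 0.0075 for rDNA delete, and 0.022 and 0.013 for the translocation. The averages had medians of -0.014, -0.031, -0.0023, -0.0038, 0.018 and 0.031 in the same order of strains. The direction of the columns was that of 5 h over 0 h for all groups but sir2 dmc1, the centring lay near 0, and the exact scale, with slopes against the scanner values from 0.671 to 1.82, stays unknown, as does the direction for sir2 dmc1. Those averages served only as an alternative without a test.

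From the processed signals, log2 of 5 h over 0 h was computed by the labelled dyes, spots with an outlier mark and control spots were left out, and each array was centred on the median of its 41282 nuclear probes (60 bases long). The 136 mitochondrial probes were kept apart. Genes and distances came from the probe annotation in the scanner files, and the genome build of these coordinates is not given in the sources used here. Gene symbols were updated through the table of assembly R64 for names only, in which 5679 of 5699 systematic names were found and 1076 symbols changed. A promoter was the mean of probes from 500 bp upstream to 100 bp downstream of the first base of an ORF. Of 5593 promoters, 5244 had values on all arrays and were tested. The median number of probes per promoter was 2, and neighbouring promoters can share probes. Probe uniqueness could not be checked, since no probe-to-genome alignment was possible without a genome.

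Region means were taken over 11 lists fixed before the data were examined, over 16 chromosomes and over 247 tiles of 50 kb with at least 20 probes. The lists were the left and right rDNA flanks (50 kb), centromeres (within 10 kb), chromosome ends (20 kb), silent mating cassettes (within 2 kb), ORF interiors (500 bp from the ends), divergent and convergent intergenic regions, and the promoters of ribosomal protein, early meiotic and classical hotspot genes. ZIP3, of the early meiotic list, had no promoter probe. Lists of rDNA repeat probes, replication origins, tRNA genes and Ty elements had been planned and were not analysed here, because the annotation names none of these features.

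Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for the correlation of blocks, on all 12 arrays in 1 fit with a mean per group and a dye term. The promoter fit had 5 residual degrees of freedom, and its prior had 9.89 degrees of freedom and a variance of 0.178. All tests were two-sided, with Benjamini-Hochberg adjustment over the 5244 promoters, the 11 lists or the 16 chromosomes, over lists, chromosomes and tiles together for tiles, and a threshold of 0.05. Flanks were also tested with limma's camera with an estimated correlation, whose p-values are unadjusted. There were 6 comparisons between groups chosen before the data were examined: each strain against dmc1, and orc1-161 dmc1 against pch2 dmc1. A further 3 were added afterwards: the arrays labelled sir2 dmc1 with the sign turned against dmc1, and rDNA delete and translocation against pch2 dmc1. Values are log2 differences ± SE from the fit. Comparisons against the same dmc1 arrays share the chance values of those arrays, so overlaps of their calls were not counted.

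Named promoters followed a rule set before the data were examined. Among promoters with an adjusted p under 0.05 and the same direction in both replicates, up to 10 with the largest increase and up to 10 with the largest decrease were named, skipping any that shared a probe with one already named. From each gene list up to 4 such promoters were named as well. Where fewer than 3 passed in a direction, the 3 with the smallest p were named as not passing. For dmc1 alone, the 10 highest and 5 lowest promoters and all classical hotspots were named. ERD2, the flank promoters TIS11, RKM5, TFS1 and RFX1 in the comparison of pch2 dmc1 with dmc1, and the 4 cassette promoters were named after their values were seen.

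The fit was tested on simulated data. For pch2 dmc1 against dmc1 over 5244 promoters, it called 7 of 67 promoters changed by 1 log2 unit, 48 of 67 changed by 2 and 66 of 66 changed by 3, and 6 of 4937 unchanged ones. A right flank raised by 1 was recovered at 1.06. In the unchanged comparisons of orc1-161, sir2, rDNA delete and translocation with dmc1 it called 0 of 5244 promoters. The simulated noise was independent between probes and arrays, with 1 common spread and no slide effect. The real arrays had median absolute log2 ratios from 0.18 (rDNA delete replicate 1) to 0.78 (dmc1 replicate 1). These rates therefore hold for the simulated noise only.

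Alternatives covered normexp background correction (offset 50) with and without loess, arrays scaled to the same median absolute deviation, centring on the 25th percentile, no dye term, the replicate number as a block, only probes well above background, medians over probes, slide and scan day as blocks, promoters from 300 or 1000 bp upstream, flanks of 20, 30 or 100 kb, camera, the authors' averages, and leaving out each array in turn. Leaving out rDNA delete replicate 2 and translocation replicate 1 together was added after the data were seen, and so was the test of 50 kb tiles with centring on the 25th percentile. The arrays lay on 9 slides scanned on 7 days. The pch2 dmc1 and sir2 dmc1 arrays each had a slide and a day of their own. The first arrays of orc1-161, rDNA delete and translocation shared a day, and so did the second arrays of these strains. Of these, rDNA delete replicate 1 and translocation replicate 1 shared a slide, as did orc1-161 replicate 2 and translocation replicate 2.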

Results

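Single-stranded DNA (ssDNA), which forms where meiotic double-strand breaks are resected, was mapped across the genome of budding yeast. All strains carried the dmc1 mutation, which blocks the strand exchange that would consume the resected ends. Each of 12 two-colour tiling arrays compared ssDNA from cells at 5 h in sporulation medium with ssDNA from the same strain at 0 h. There were 6 groups of 2 arrays: dmc1 alone, pch2 dmc1, sir2 dmc1, orc1-161 dmc1, dmc1 with the ribosomal DNA (rDNA) deleted, and dmc1 with a reciprocal translocation between chromosomes II and XII. The labels call the arrays of a group biological replicates and do not state whether they came from separate cultures. Values are log2 ratios of 5 h over 0 h relative to each array's median, at 41282 nuclear probes spaced 267 bp apart (median), so they show relative enrichment along the genome and not absolute amounts of ssDNA. The number of arrays, 2 per group, limits the precision. Both dmc1 arrays lay on 1 slide that held no other group, so dmc1 and its slide cannot be told apart in any comparison against dmc1. The channel labelled 0 h of dmc1 replicate 2 had only 6985 probes well above background. Neighbouring probes correlated at r = 0.28 and 0.41 in the dmc1 arrays, the reference of every comparison against dmc1. In the pch2 dmc1 arrays they correlated at 0.91 and 0.49, and the lowest value was 0.097, in rDNA delete replicate 2. The pch2 dmc1 and sir2 dmc1 arrays were processed with Feature Extraction 9.1.3.1 and all others with 10.1.1.1. Strain and software version thus cannot be told apart where either of these groups is compared with a group outside them.

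The probes inside DMC1, which encodes the meiosis-specific recombinase, were dim in all 12 arrays, from -0.60 (translocation replicate 1) to -3.37 (sir2 dmc1 replicate 2) on the log2 scale against the array median. PCH2, which encodes a meiotic checkpoint ATPase, was dim in the pch2 dmc1 arrays (-1.61 and -1.55) and bright in the dmc1 arrays (0.81 and 0.61). PCH2 was also dim in arrays whose labels do not name it: -3.06 in rDNA delete replicate 1, -2.87 in rDNA delete replicate 2, where 1 of its 6 probes was usable, and -1.64 in translocation replicate 2. In translocation replicate 1 it stood at -0.0047. The authors' table names pch2 in its columns for both of these strains, so they were compared with pch2 dmc1 as well as with dmc1. SIR2, which encodes a silencing histone deacetylase, was not dim in the arrays labelled sir2 dmc1 but brighter than 98.8% and 99.6% of genes there (1.38 and 1.40), against 0.18 to 0.70 in the other arrays. This goes against a full deletion of the gene, but the name sir2 dmc1 does not state the allele. TRP1 was also bright in these 2 arrays (1.86 and 1.73, against 1.00 or lower in the others). Whether the brightness of the 2 genes is linked was not tested. The rDNA deletion could not be checked in this way, because no probe lay in the 22493 bp between the outermost probes beside the repeats (451429 and 473923 on chromosome XII).

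**Figure D1:**
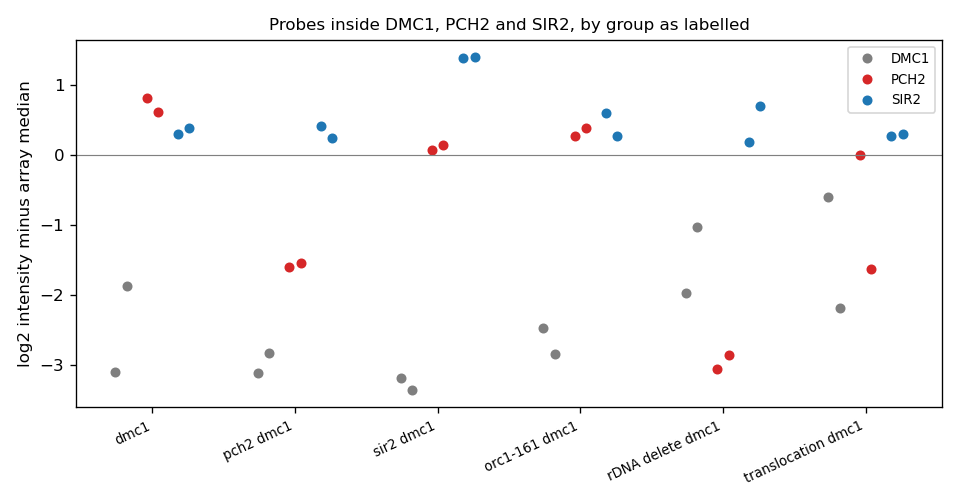
Mean log2 intensity of both channels over the probes inside DMC1, PCH2 and SIR2, minus the array's median (vertical axis), for each array of the 6 groups as labelled (1 point per array and gene). DMC1 lies below the median in all 12 arrays, PCH2 lies at -1.55 or lower in 5 arrays of 3 groups, and SIR2 is highest in the arrays labelled sir2 dmc1 (1.38 and 1.40).

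The arrays labelled sir2 dmc1 have no settled direction. Their log ratios, turned by the labelled dyes, correlated negatively across probes with every other array (r from -0.17 to -0.79) and positively with each other (0.72). The channel labelled 5 h was the brighter one in 0 of these 2 arrays and in 10 of the 10 others. The authors' table columns for the 2 replicates followed the array of the other replicate (r = -0.97 and -0.99) more closely than their own (-0.70 and -0.71). The comparisons of these arrays with dmc1 over promoters and region lists are therefore given both with the sign turned and as labelled.

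In dmc1 cells, the promoter with the highest 5 h enrichment was that of PHO8, a vacuolar alkaline phosphatase gene (log2 4.24 ± 0.31 SE, n = 2, adjusted p = 4.61e-06). BSC1 (3.53), TIR3 (3.31), YER152C (3.27), the branched-chain amino acid gene ILV3 (3.15), YPL247C (3.15), DEP1 (3.02), ATG23 (3.01), OYE2 (3.01) and the DNA glycosylase gene NTG1 (2.997) followed. The promoters of 12 genes at classical recombination hotspots averaged 1.22 ± 0.15 (adjusted p = 6.87e-07), and 8 of the 12 were enriched, among them IMG1 (2.41 ± 0.34), CCT6 (2.18 ± 0.35), CYS3 (2.17 ± 0.34) and ARG4 (1.58 ± 0.35). BUD23 and ARE1, which share their probes, both stood at 1.40, HIS2 at 1.39 and DED81 at 1.09. HIS4 (0.89, adjusted p = 0.0682), GAT1 (0.86, 0.0727) and CHA1 (-0.61, 0.158) did not pass, and FUS1 was depleted (-1.38 ± 0.32, adjusted p = 0.00763). The call of the hotspot list was lost with arrays scaled to the same spread (0.79, adjusted p = 0.167) and with bright probes alone (0.31, 0.567), the highest of a range that began at 6.62e-35. The lowest promoters were those of YBL039W-A (-3.45), YEL073C (-2.88), SSQ1 (-2.47), HSM3 (-2.43) and AAD3 (-2.42).

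Among regions of dmc1 cells, divergent intergenic regions, which hold the promoters of both neighbouring genes, were enriched (0.32 ± 0.11, adjusted p = 0.0137). ORF interiors (-0.32 ± 0.11, 0.0137), convergent intergenic regions (-0.32 ± 0.12, 0.0226), the silent mating cassettes (-0.32 ± 0.10, 0.0137), chromosome ends (-0.33 ± 0.14, 0.032) and centromeres (-0.24 ± 0.11, 0.0433) lay below the array median. So did the 50 kb to the left (-0.54 ± 0.11, adjusted p = 0.000309) and to the right (-0.43 ± 0.11, 0.00291) of the rDNA. Each of these depleted lists lies above 0 when arrays are centred on their 25th percentile, for example the left flank at 0.25 and the right flank at 0.36, so the signs hold against the median probe only. With arrays scaled to the same spread, the calls of all these region lists but the left flank were lost, and with bright probes alone those of all but the cassettes, which had no value there. Calls were also lost for centromeres, ends and convergent regions with normexp and for centromeres, ends and the right flank with loess. They were lost for centromeres, ends, convergent regions and cassettes with medians over probes and for centromeres and divergent regions without rDNA delete replicate 2 and translocation replicate 1. With normexp, loess, medians over probes and this omission, the adjusted p of the lost calls ran from 0.0522 to 0.299. Early meiotic promoters (0.15, adjusted p = 0.213) and ribosomal protein promoters (-0.14, 0.213) did not pass. In total 758 of 5244 promoters were enriched and 345 depleted in limma's test against 0. With arrays scaled to the same spread, limma called 13 enriched and 0 depleted, with 950 at an unadjusted p under 0.05, and 340 were enriched without dmc1 replicate 1 and 501 without dmc1 replicate 2. Without dmc1 replicate 1 the calls of ORF interiors, chromosome ends, centromeres, convergent regions and the right flank were lost, and without dmc1 replicate 2 those of divergent and convergent regions, cassettes, ends and centromeres. Those of convergent regions, cassettes, ends and centromeres were also lost without either pch2 dmc1 array, and that of centromeres without either orc1-161 or either translocation array.

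Loss of PCH2 was compared with dmc1 alone. In pch2 dmc1 cells ssDNA was higher on both sides of the rDNA, by 0.99 ± 0.14 (log2, SE) over the 177 probes of the left flank and by 1.32 ± 0.15 over the 130 probes of the right flank (adjusted p = 5.91e-06 and 1.96e-07 over 11 lists, both replicates of each side above both dmc1 replicates). The group means were 0.44 and 0.89 in pch2 dmc1 against -0.54 and -0.43 in dmc1. Next to the repeats, the promoters of ACS2 (YLR153C, acetyl-CoA synthetase, 447453 to 447962 on chromosome XII) and RNH203 (YLR154C, an RNase H2 subunit, 448423 to 448600) rose by 2.94 ± 0.48 and 2.80 ± 0.41 (adjusted p = 0.0396 and 0.0312). Of 21 promoters tested on each side, 2 rose on the left and 0 on the right in the test over all genes, and adjusted over the list alone 11 rose on the left and 13 on the right. Among flank promoters that did not pass over all genes, TIS11 and RKM5 (shared probes) stood at 2.46, TFS1 at 2.19 and RFX1 at 1.93.

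Away from the rDNA flanks, YBL039W-A and ERD2, which share their probes on chromosome II, were the only other promoters to rise in pch2 dmc1 cells (2.997 ± 0.51, adjusted p = 0.0396). YBL039W-A was the lowest promoter of dmc1 (-3.45). The decreases with the smallest p, at OMA1 (-1.83), YPL245W (-1.72) and JSN1 (-1.84), did not pass (adjusted p = 0.228 each). Classical hotspot promoters differed by 0.17 ± 0.20 (adjusted p = 0.668, 0 of 12 passing and 1 higher adjusted over the list alone), ribosomal protein promoters by 0.092 (0 of 128 passing) and early meiotic promoters by 0.061 (0 of 22 passing). Of 247 tiles of 50 kb, 5 rose in limma's test, 3 of them around the rDNA (up to 1.36 ± 0.16 at 450001 to 500000), with the others at the start of chromosome III (0.73) and near the end of chromosome XII (0.77, 1050001 to 1100000). With centring on the 25th percentile 1 of these 5 passed, at 450001 to 500000 (0.99). Over all promoters, limma called 4 higher and 0 lower, with 579 at an unadjusted p under 0.05. Normexp gave 49 higher and 18 lower and normexp with loess 20 and 17. All these calls were lost with arrays scaled to the same spread, with centring on the 25th percentile, with promoters from 300 bp upstream and without rDNA delete replicate 2 and translocation replicate 1, where limma called 0 (281 to 750 at an unadjusted p under 0.05), and with bright probes alone (0, with 1 at an unadjusted p under 0.05). The count was 133 without dmc1 replicate 2, 2 without pch2 dmc1 replicate 1 or either rDNA delete array, and 0 without dmc1 replicate 1, pch2 dmc1 replicate 2 or any one of the sir2 dmc1 and orc1-161 dmc1 arrays (246 to 501 at an unadjusted p under 0.05 in limma). Both flank calls held with an estimated correlation (p = 0.014 left and 0.00112 right). Of the alternatives tested, they ended with the 457 probes that were well above background in both channels of all 12 arrays (0.47 left and 0.83 right, adjusted p = 0.572 each, the highest of a range that began at 3.85e-08 left and 8.57e-13 right).

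**Figure D2:**
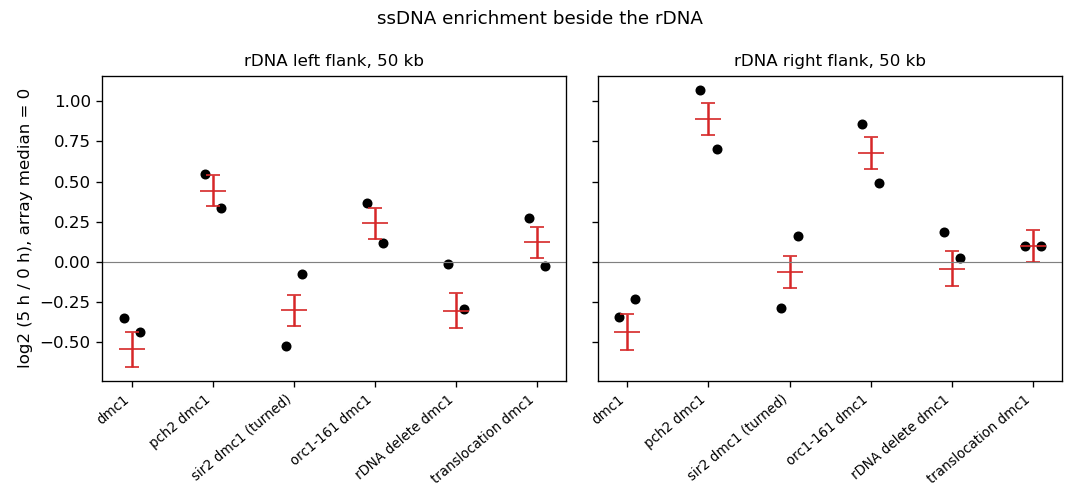
Mean log2 ratio of 5 h over 0 h, with each array's median at 0 (vertical axis), over the probes within 50 kb to the left and to the right of the rDNA, for the 6 groups with the arrays labelled sir2 dmc1 turned. Black points are single arrays and red bars the limma group means ± SE after the dye term, which lie apart from the points where both arrays of a group had the same dyes (dmc1 and rDNA delete). The pch2 dmc1 means (0.44 and 0.89) lie highest and the dmc1 means (-0.54 and -0.43) lowest.

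The orc1-161 allele of ORC1, the gene of the largest subunit of the origin recognition complex, gave higher ssDNA at the same place. The left flank of the rDNA was higher than in dmc1 by 0.79 ± 0.14 and the right flank by 1.11 ± 0.15 (adjusted p = 0.000127 and 3.06e-06, p = 0.0294 and 0.00171 with an estimated correlation). ACS2 rose by 3.38 ± 0.48 and RNH203 by 3.19 ± 0.41 (adjusted p = 0.00995 and 0.00665). They were the 2 promoters that limma called higher, with 0 lower and 526 at an unadjusted p under 0.05. Normexp gave 20 higher and 4 lower and normexp with loess 9 and 3, promoters from 300 bp upstream gave 1 higher, and with bright probes alone limma called 0, with 0 at an unadjusted p under 0.05. Adjusted over the list alone, 7 of 21 left and 8 of 21 right flank promoters rose. YBL039W-A (2.88, adjusted p = 0.0599), the maltase gene MAL32 (2.35, 0.0762) and YCL049C (2.46, 0.0802) did not pass, nor did PHO8 (-1.90, 0.238), LOT5 (-1.80, 0.255) and VIR1 (-1.54, 0.255) among the decreases. Hotspot promoters differed by -0.085 ± 0.20 (adjusted p = 0.741). Among 50 kb tiles 15 rose, including the start (0.97) and the end (0.77) of chromosome III, and 3 tiles around the rDNA (up to 1.19). With centring on the 25th percentile 1 of the 15 passed, at 450001 to 500000 of chromosome XII (0.79), and 11 other tiles were lower. Within the 2 scan days that held orc1-161 arrays together with rDNA delete and translocation arrays, orc1-161 lay above the mean of those groups by 0.24 and 0.28 on the left and by 0.72 and 0.43 on the right. On the left, the differences were 0.38 and 0.41 from rDNA delete but only 0.093 and 0.14 from the translocation. The left flank call ended with centring on the 25th percentile (0.38, adjusted p = 0.187) and both flank calls with bright probes alone (0.43 and 0.97, 0.622 and 0.531), over ranges of adjusted p that began at 9.64e-07 left and 2.31e-09 right. The promoter count was 104 without dmc1 replicate 2, 4 without either pch2 dmc1 array, 1 without dmc1 replicate 1 and 0 in limma without orc1-161 replicate 1 (173 at an unadjusted p under 0.05).

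Set directly against pch2 dmc1, orc1-161 dmc1 did not differ past the threshold on the left (-0.20 ± 0.14) or the right (-0.21 ± 0.14) of the rDNA (adjusted p = 0.519 for both). The promoter differences with the smallest p, at ASK1 (1.15), DPM1 (1.32), SEC63 (1.11), YIG1 (-1.28), SEC4 (-1.47) and HOR7 (-1.35), did not pass. limma called 0 of 5244 promoters, with 70 at an unadjusted p under 0.05. The silent cassettes (0.25, adjusted p = 0.519) and hotspot promoters (-0.25, 0.519) did not differ past the threshold either. With loess, 20 kb flanks or bright probes alone the right flank difference took the other sign (0.0095, 0.069 and 0.14).

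For the arrays labelled sir2 dmc1 with the sign turned, the silent mating cassettes HML and HMR, which Sir2 keeps silent, were higher than in dmc1, a difference that did not pass with the direction as labelled (0.12 ± 0.14, adjusted p = 0.378). The cassette regions rose by 0.51 ± 0.14 (25 probes, adjusted p = 0.0157), and adjusted over the list alone 4 of 4 cassette promoters (HMLALPHA1, HMLALPHA2, HMRA1 and HMRA2) rose, against 0 of 4 in limma over all genes. The 4 promoters lie in 2 cassettes, where neighbouring promoters can share probes, so they are not 4 separate observations. Probe uniqueness was not checked, so signal from like sequences elsewhere cannot be excluded. The rDNA flanks did not pass, at 0.24 ± 0.14 on the left and 0.37 ± 0.15 on the right (adjusted p = 0.288 and 0.112). YBL039W-A rose (3.18 ± 0.51, adjusted p = 0.0409) together with ERD2 on the same probes, and limma called these 2 promoters higher and 0 lower, with 660 at an unadjusted p under 0.05. Normexp gave 95 higher and 35 lower and normexp with loess 44 and 16. These calls were lost, with 0 in limma, when arrays were scaled to the same spread or centred on the 25th percentile, with promoters from 300 or 1000 bp upstream and without rDNA delete replicate 2 and translocation replicate 1 (367 to 868 at an unadjusted p under 0.05), and with bright probes alone (0 at an unadjusted p under 0.05). THR4 (3.19), RPL27A (2.07), LTE1 (2.01), SCW4 (-1.82), BSC1 (-2.18) and BAT1 (-1.58) did not pass. Hotspot promoters differed by 0.16 ± 0.20 (adjusted p = 0.515). The cassette call was lost with arrays scaled to the same spread (0.34, adjusted p = 0.508), with centring on the 25th percentile (0.19, 0.71), with normexp (0.43, 0.218) and with medians over probes (0.56, 0.0766), over a range from 0.00423 to 0.71, and without dmc1 replicate 2 (0.43, 0.111) or either pch2 dmc1 array (0.49, 0.0767). Without the array labelled sir2 dmc1 replicate 1 the right flank passed (0.45, adjusted p = 0.0235), and the promoter count was 166 without dmc1 replicate 2 and 0 in limma without any one of the 9 arrays other than this and the pch2 dmc1 arrays (320 to 778 at an unadjusted p under 0.05).

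With the direction as labelled, the same arrays gave 465 promoters higher and 1401 lower than dmc1. With the sign turned the numbers were 2 and 0. As labelled, their map ran against that of dmc1, so promoters high in dmc1 tended to fall and low ones to rise. Of those named next, PHO8, TIR3, NTG1, DEP1, YER152C and ILV3 were among the highest promoters of dmc1. YBL039W-A, YEL073C and AAD3 were among its lowest. While the direction is unsettled, these differences cannot be read as an effect of the strain. The largest decreases were at PHO8 (-7.03 ± 0.42), TIR3 (-6.33), NTG1 (-5.90), DEP1 (-5.83), YER152C (-5.67), TAH1 (-5.63), ILV3 (-5.43), DUR12 (-5.35), FRS2 (-5.30) and ERG11 (-5.28). The largest increases were at YBL039W-A (3.72), YEL073C (3.58), PAU20 (3.21), BDS1 (3.17), AAD3 (3.15), YOL163W (2.98), GAL10 (2.85), ENA2 (2.81), MED8 (2.72) and TTI1 (2.65). Hotspot promoters lay -2.60 ± 0.20 below dmc1 (adjusted p = 2.35e-10), with 9 of 12 lower, among them IMG1 (-4.82), CYS3 (-4.55), CCT6 (-3.64) and ARG4 (-3.15), and adjusted over the list alone 1 rose and 10 fell. This list call was lost with bright probes alone (-0.76, adjusted p = 0.337). In this direction the left flank was higher by 0.84 ± 0.14 and the right by 0.50 ± 0.15 (adjusted p = 5.13e-05 and 0.00685), and neither passed with an estimated correlation (p = 0.118 and 0.162). The right call was also lost in 6 further alternatives (adjusted p = 0.0853 to 0.388). The right flank did not pass without dmc1 replicate 1 (0.44, adjusted p = 0.059) or the array labelled sir2 dmc1 replicate 1 (0.37, 0.0791), and without the latter 1089 promoters passed. The silent cassettes did not pass, and 0 of their 4 promoters lay above 0 (median -0.52). Chromosome ends (0.56), ORF interiors (0.52) and convergent regions (0.435) passed as higher and divergent regions (-0.80) as lower, which none did with the sign turned. All these calls were lost with bright probes alone, and those of ends, ORF interiors and convergent regions with centring on the 25th percentile. On the left flank 6 of 21 promoters rose, including SLX4 (1.75), PDC5 (1.68), YLR152C (1.45) and ACS2 (1.37), and adjusted over the list alone 5 did. On the right flank 2 rose (RRT15 at 1.46 and PUS5 at 1.08) and 4 fell, including YLR177W (-1.56) and YLR179C (-1.22), and adjusted over the list alone 0 rose and 1 fell. Of 128 ribosomal protein promoters 18 rose and 13 fell, including RPL32 (-2.27), RPL15B (-2.24), RPS8A (-2.22) and RPL1A (-2.17), and adjusted over the list alone 15 rose and 13 fell. Of 22 early meiotic promoters 1 rose (REC114, 2.06) and 5 fell, including MSH4 (-1.99), RIM4 (-1.99) and MEI4 (-1.24), and adjusted over the list alone 1 rose and 2 fell.

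The arrays labelled rDNA delete dmc1 were compared with dmc1 and, because PCH2 was dim in them, with pch2 dmc1. Beside the deleted repeats, ssDNA was lower than in pch2 dmc1 by -0.75 ± 0.14 on the left and -0.93 ± 0.15 on the right (adjusted p = 0.000165 and 4.11e-05), and the left call was lost with an estimated correlation (p = 0.0883). Classical hotspot promoters were also lower than in pch2 dmc1 (-1.02 ± 0.20, adjusted p = 0.000165) and than in dmc1 (-0.85 ± 0.19, 0.00197), a difference from dmc1 that takes the other sign when arrays are scaled to the same spread (0.16, adjusted p = 0.852). The hotspot call against pch2 dmc1 was lost with loess (-0.55, adjusted p = 0.128), with arrays scaled to the same spread (-0.55, 0.474) and with bright probes alone (-1.32, 0.623). The call against dmc1 was also lost with loess (-0.71, 0.0683) and bright probes alone (-0.66, 0.931). It was lost as well with the omission of rDNA delete replicate 2 and translocation replicate 1 (-0.57). The ranges of adjusted p began at 3.12e-05 against pch2 dmc1 and 2.76e-08 against dmc1. Adjusted over the list alone, 4 left and 10 right flank promoters of 21 each fell against pch2 dmc1, while over all genes limma called 0 promoters, with 396 at an unadjusted p under 0.05. It called 2 higher and 144 lower with normexp, and 12 lower without rDNA delete replicate 1. ACS2 (-2.55), RFX1 (-2.07) and RNH203 (-2.00), which had the smallest p, did not pass (adjusted p = 0.312 each), nor did FCY22 (1.40), PMT5 (1.27) and SVP26 (1.43). Tiles of 50 kb fell at 6 places, 3 of them around the rDNA. With centring on the 25th percentile 2 of the 6 passed, and for the translocation 0 of the 4 tiles that were lower than in pch2 dmc1 and 0 of the 2 higher than in dmc1. Against dmc1, this centring called 54 tiles lower for rDNA delete and 8 for the translocation, where the median called 0 lower. Both flank calls against pch2 dmc1 were lost with bright probes alone (-0.525 and -0.66, adjusted p = 0.712 each, the highest of ranges that began at 8.3e-06 left and 3.75e-05 right).

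Against dmc1, the flanks of the deleted rDNA differed by 0.24 ± 0.14 on the left (adjusted p = 0.165) and 0.39 ± 0.14 on the right (0.0442). The right flank call was lost with an estimated correlation (p = 0.281), under most other alternatives, and without any one of the dmc1, pch2 dmc1 and rDNA delete arrays (0.31 to 0.48, adjusted p = 0.0635 to 0.222). A total of 47 promoters rose and 77 fell in limma's test. The split was 161 and 422 with normexp and 43 and 481 with centring on the 25th percentile, and 0 and 2 both with bright probes alone and without rDNA delete replicate 2 and translocation replicate 1. Among the largest increases were those at the threonine synthase gene THR4 (3.16 ± 0.56), YBL039W-A (2.94), YEL073C (2.74), HSM3 (2.74), SSQ1 (2.74), SGF73 (2.71), RRG9 (2.19), AAD3 (2.16) and PBP1 (2.16). The largest decreases were at YLL053C (-2.91 ± 0.41), BSC1 (-2.83), the aquaporin gene AQY2 (-2.70), PHO8 (-2.70), the ribonucleotide reductase gene RNR2 (-2.64), YER152C (-2.60), SMM1 (-2.55), SCW4 (-2.51), the chaperonin gene CCT4 (-2.50) and YML100W-A (-2.44). Of these promoters, YBL039W-A, YEL073C, HSM3, SSQ1 and AAD3 were also the lowest of dmc1, and PHO8, BSC1 and YER152C were among its highest. The log2 ratios had an SD of 1.27 and 1.01 in the dmc1 arrays and of 0.31 and 0.94 in the rDNA delete arrays. Among hotspots CCT6 fell (-2.11 ± 0.44, adjusted p = 0.0279), and adjusted over the list alone 1 of 12 rose and 4 fell. The ribosomal protein promoters RPL7A (2.05) and RPL27A (1.83) rose. Convergent intergenic regions were higher by 0.41 ± 0.15 (adjusted p = 0.0442), a call lost in most alternatives. Without rDNA delete replicate 2, whose neighbouring probes barely correlated (r = 0.097), 1 promoter passed, and with arrays scaled to the same spread limma called 0, with 512 at an unadjusted p under 0.05. The count was 340 without dmc1 replicate 2, 276 without rDNA delete replicate 1, 13 without dmc1 replicate 1, 12 without either pch2 dmc1 array and 11 without either orc1-161 array, and the hotspot call was lost without either dmc1 array or rDNA delete replicate 2.

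The arrays labelled translocation dmc1, from cells in which parts of chromosomes II and XII are exchanged, differed from both references beside the rDNA. Against dmc1, the left flank was higher by 0.67 ± 0.14 and the right flank by 0.53 ± 0.15 (adjusted p = 0.0017 and 0.00964). With an estimated correlation the left call held (p = 0.0367) and the right was lost (p = 0.0763). The right call was also lost without dmc1 replicate 1 (0.48, adjusted p = 0.101) or translocation replicate 2 (0.385, 0.136) and in 7 further alternatives (0.0677 to 0.849). The left call was lost with centring on the 25th percentile (0.45, adjusted p = 0.111), without the dye term (0.52, 0.073) and with bright probes alone (0.37, 0.926), over a range that began at 0.000125. Against pch2 dmc1 the right flank was lower by -0.79 ± 0.14 (adjusted p = 0.000162, p = 0.0029 with an estimated correlation). This call was lost with bright probes alone (-0.19, adjusted p = 0.916, the highest of a range that began at 0.000108). The left differed by -0.32 ± 0.14 (adjusted p = 0.0737), which passed without either array labelled sir2 dmc1 (0.0339) and, among the alternatives, with normexp, with arrays scaled to the same spread and with flanks of 20 or 30 kb (0.00279 to 0.0421). Adjusted over the list alone, 7 of 21 left and 1 of 21 right flank promoters rose against dmc1, and 8 of 21 right flank promoters fell against pch2 dmc1. Neither whole chromosome differed from dmc1 (chromosome II 0.069 ± 0.14, chromosome XII 0.12 ± 0.14, adjusted p = 0.699 for both). The place of the exchange is not given in the sources used here, so the probes beside it could not be tested.

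Single promoters of the translocation strain that rose against dmc1 were YBL039W-A with ERD2 on the same probes (2.95 ± 0.51), ABP140 (2.51), SAM37 (2.30) and the mismatch repair gene PMS1 (2.05), and those that fell were YER152C (-3.67 ± 0.67), BSC1 (-2.99) and PHO8 (-2.37), all at an adjusted p of 0.047. Of these, YBL039W-A was also the lowest promoter of dmc1, and YER152C, BSC1 and PHO8 were among its highest. Hotspot promoters were lower than in pch2 dmc1 (-0.64 ± 0.19, adjusted p = 0.0146), a call lost with loess (-0.36, 0.26), with arrays scaled to the same spread (-0.835, 0.239), with centring on the 25th percentile (-0.48, 0.0802) and with bright probes alone (-0.71, 0.916), over a range that began at 0.00284. Against dmc1 they did not pass (-0.47 ± 0.20, 0.102). Against pch2 dmc1, limma called 0 promoters, with 400 at an unadjusted p under 0.05 (71 lower with normexp), and RNA14 (1.49), PPQ1 (1.50), ASC1 (1.53), PCK1 (-2.33), YIG1 (-1.75) and SWC3 (-1.81) did not pass. The split against dmc1 was 46 higher and 178 lower with normexp, 24 and 114 with normexp and loess, 3 and 14 with centring on the 25th percentile, 44 and 44 without the dye term and 120 and 159 with the slide as a block. It was 0 and 0 in limma, which ended every call named above, with arrays scaled to the same spread, medians over probes, promoters from 300 or 1000 bp upstream and the omission of rDNA delete replicate 2 and translocation replicate 1 (313 to 1019 at an unadjusted p under 0.05), and with bright probes alone (2 at an unadjusted p under 0.05). The count against dmc1 was 131 without dmc1 replicate 2, 44 without translocation replicate 2, 2 without either pch2 dmc1 array, and 0 in limma without translocation replicate 1 or any one of the sir2 dmc1, orc1-161 and rDNA delete arrays (442 to 1003 at an unadjusted p under 0.05). Translocation replicate 1 had 1003 probes well above background in its 0 h channel, and the hotspot call against pch2 dmc1 was lost without it or either dmc1 array (-0.65 and -0.64, adjusted p = 0.0606 and 0.0866).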

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

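All tests of differences between strains and of explanations in this part were chosen after the results were seen. The arrays labelled sir2 dmc1 are used here with the sign turned except where values as labelled are given, and differences were tested by limma contrasts adjusted over 20 tests.

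The regions beside the rDNA differed between the mutant strains themselves, which is what singled out the next results. On the left and right flank, pch2 dmc1 lay above sir2 dmc1 by 0.74 and 0.95 (adjusted p = 0.000113 and 2.38e-05), above rDNA delete by 0.75 and 0.93 (0.000148 and 3.74e-05) and above the translocation by 0.32 and 0.79 (0.0445 and 9.84e-05). With camera and an estimated correlation, the left differences from rDNA delete (p = 0.0883) and from the translocation (p = 0.408) did not pass, while both right ones did (p = 0.00207 and 0.0029). As labelled, pch2 dmc1 lay above sir2 dmc1 by 0.14 and 0.83 (0.405 and 7.99e-05). With the sign turned, the sir2 dmc1 arrays lay below orc1-161 dmc1, at -0.54 and -0.74 (0.00158 and 0.000135), and on the left below the translocation, at -0.42 (0.00982). As labelled, they stood at 0.058 and -0.61 against orc1-161 dmc1 (0.71 and 0.000872) and on the left at 0.18 against the translocation (0.299), so both left differences took the other sign. Also as labelled, sir2 dmc1 lay above rDNA delete on the left by 0.60 (0.00121), against 0.0027 (0.985) with the sign turned, and the left difference of pch2 dmc1 from the translocation had an adjusted p of 0.0524. The orc1-161 dmc1 arrays lay above rDNA delete by 0.54 and 0.72 (0.00233 and 0.00027) and on the right above the translocation by 0.58 (0.00123). On the left their difference from the translocation did not pass (0.12, 0.438). On the left, rDNA delete lay below the translocation, at -0.43 (0.0129). Within the 2 scan days these 3 groups shared, single arrays of orc1-161 dmc1 differed from rDNA delete by 0.38 and 0.41 on the left and 0.67 and 0.47 on the right. They differed from the translocation by 0.093 and 0.14 on the left and 0.76 and 0.39 on the right. The rDNA delete arrays differed from the translocation by -0.285 and -0.26 on the left.

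The 136 mitochondrial probes, which no comparison used, were singled out because they lay higher than in dmc1 in these 3 groups: orc1-161 dmc1 (mean -0.76), rDNA delete (-0.84) and the translocation (-0.64), against -1.25 and -1.54 in the dmc1 arrays. The arrays labelled sir2 dmc1 lay above dmc1 too as labelled (2.49 and 1.33), but not with the sign turned (-2.49 and -1.33).

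A first pattern is the higher ssDNA beside the rDNA in pch2 dmc1 and orc1-161 dmc1 than in dmc1. Cross-hybridisation of the repeats to neighbouring probes is argued against by the part of the flanks 10 to 50 kb away, where the lower of the 2 strain differences was 0.84 ± 0.14. A peculiarity of the dmc1 slide stays open: pch2 dmc1 minus sir2 dmc1 turned, a difference without dmc1 arrays, was 0.85 ± 0.13 SE over both flanks, but it was 0.48 ± 0.13 as labelled, orc1-161 dmc1 minus the translocation was 0.35 ± 0.13, and all 5 other groups lay above dmc1 on both flanks. A peculiarity of the slides and scan days of pch2 dmc1, which held no other group, was not tested. Nor was the software version, which differed between the pch2 dmc1 arrays (9.1.3.1) and the dmc1 arrays (10.1.1.1). The orc1-161 dmc1 arrays had the same version as dmc1. An effect of the mutations on break formation beside the rDNA is a hypothesis that stays open and was not tested further.

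A second pattern is that the arrays labelled sir2 dmc1 run against all others. Reversed dye labels with the files in place are argued against, since the authors' table columns followed their own arrays less closely than the exchanged ones (difference in size of r -0.29). An inverted map in these cells, with files and columns in place, is argued against by the same values. It would leave each column closest to its own array. The columns followed their own arrays at -0.70 and -0.71 and the exchanged ones at -0.97 and -0.99. The lowest correlation of the table columns of sir2 dmc1 with those of dmc1 was 0.43. It decides nothing here, because the direction of those columns is itself unknown. An exchange of the 2 replicates' files, which would turn both signs, stays open as a candidate explanation. The gap in size of r was 0.26 in favour of the exchanged files. Bright SIR2 probes in these arrays are not accounted for by such an exchange.

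A further pattern is that PCH2 was dim in arrays labelled rDNA delete and translocation. Weak hybridisation of rDNA delete replicate 1 and translocation replicate 2 is argued against: of 675 other genes that were bright in both dmc1 arrays, 0% lost as much intensity there as PCH2 (-3.78 and -2.35 against its dmc1 mean), and the largest losses among them were -1.55 and -1.32. In rDNA delete replicate 2 PCH2 rests on 1 usable probe, so weak hybridisation stays open there. Strains that also lack PCH2 stay open as a candidate explanation, since the higher percentile of PCH2 in rDNA delete replicate 1 and translocation replicate 2 was 0.144. In these 2 arrays the probes 538, 856, 1166 and 1268 bp into PCH2 were dim (-4.97 to -1.94 and -3.08 to -3.04), as in pch2 dmc1. The probe at 1769 bp was bright (0.71 and 0.82), also as in pch2 dmc1 (0.33 and 0.29). That at 274 bp was bright in translocation replicate 2 (1.56) but not in pch2 dmc1 (-0.80 and -0.15). Differences of both strains from dmc1 can thus not be put down to the rDNA deletion or the translocation alone. Translocation replicate 1, where PCH2 stood at the 35.5th percentile, had few probes above background. DMC1 still lay at percentile 2.68 and LYS2 at 5.05 in that array. Whether the 2 translocation arrays differ in PCH2 stays open.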

How the results depend on the processing

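All alternatives here were chosen before the data were examined except for the omission of rDNA delete replicate 2 and translocation replicate 1 together, the turned sign of the arrays labelled sir2 dmc1, and the comparisons of rDNA delete and translocation with pch2 dmc1, which were chosen after seeing the data. Below, strains are named without dmc1 and compared with dmc1 where no other reference is given, flanks are those of the rDNA, values are log2 differences followed by adjusted p, and the cause of a change was not tested unless it is stated. Promoter counts within 1.5 times of the reported count are not listed.

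The higher flanks of pch2 passed the threshold on both sides under every alternative but bright probes alone, and those of orc1-161 under every alternative but bright probes alone and, on the left, centring on the 25th percentile. The authors' averages (no test) had the same sign for both. The filter for bright probes left 457 probes and 69 promoters, so its losses come with far fewer values, and it gave no value for the silent cassettes (10 of 11 lists). Signal over background limits what dim arrays show. At 0 h, 1003 probes lay well above background on translocation replicate 1, 6985 on dmc1 replicate 2 and 41258 on sir2 replicate 2. Lists of rDNA repeat probes, replication origins, tRNA genes and Ty elements, and a filter for probe uniqueness, had been planned and were not run. With the scan day as a block (correlation 0.00704 for promoters and 0.0228 for regions) no call of a flank, chromosome, list or named promoter changed, though promoter counts did (749 enriched and 337 depleted for dmc1), and the correlation for slides was negative (-0.36 and -0.45).

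Adjusted p over the alternatives ran, for the left flank, from 3.85e-08 to 0.572 for pch2, 9.64e-07 to 0.622 for orc1-161, 1.52e-05 to 0.0333 for sir2 as labelled, 0.141 to 0.944 for sir2 turned, 0.0322 to 0.931 for rDNA delete and 0.000125 to 0.926 for translocation. For the right flank the ranges were 8.57e-13 to 0.572 for pch2, 2.31e-09 to 0.531 for orc1-161, 0.000732 to 0.388 for sir2 as labelled, 0.0453 to 0.855 for sir2 turned, 0.03 to 0.931 for rDNA delete and 0.00271 to 0.849 for translocation. Against pch2 they were, left and right, 0.191 to 0.945 and 0.266 to 0.955 for orc1-161, 8.3e-06 to 0.712 and 3.75e-05 to 0.712 for rDNA delete, and 0.00279 to 0.935 and 0.000108 to 0.916 for translocation. Chromosomes II and XII of the translocation had 0.599 to 0.907 and 0.588 to 0.907.

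Centring on the 25th percentile moved the median of all promoters by 0.79 for dmc1, -0.37 for pch2, -0.40 for orc1-161, -0.25 for sir2 as labelled, -0.315 for sir2 turned, -0.33 for rDNA delete, -0.21 for translocation and 0.16 for translocation against pch2. Bright probes alone moved it by -0.30 for dmc1, 0.63 for sir2 as labelled, -0.62 for rDNA delete, -0.23 for translocation, and, against pch2, by 0.13 for orc1-161, -0.60 for rDNA delete and -0.14 for translocation. Scaling to the same spread moved rDNA delete by 0.16, loess moved pch2 by -0.11. The joint omission moved translocation by 0.16 against dmc1 and 0.13 against pch2. The split of higher against lower promoters went from 758 and 345 to 2703 and 51 for dmc1 with the 25th percentile and to 13 and 0 with scaling. With the 25th percentile it went from 47 and 77 to 43 and 481 for rDNA delete, from 5 and 3 to 3 and 14 for translocation, and from 465 and 1401 to 283 and 1638 for sir2 as labelled.

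With normexp, promoter counts were 1158 for dmc1, 67 for pch2, 24 for orc1-161, 130 for sir2 turned, 583 for rDNA delete, 224 for translocation, 146 for rDNA delete against pch2 and 71 for translocation against pch2. Calls were lost for the right flank of sir2 as labelled (0.31, 0.0994), rDNA delete (0.36, 0.0779) and translocation (0.42, 0.0677). The left flank of translocation against pch2 (-0.43, 0.0138) newly passed. With normexp and loess, promoter counts were 1140 for dmc1, 37 for pch2, 12 for orc1-161, 60 for sir2 turned, 402 for rDNA delete and 138 for translocation. The sign turned for the right flank of orc1-161 against pch2 (0.0095, 0.955). The right flank of sir2 as labelled (0.35, 0.0881), rDNA delete (0.37, 0.0691) and translocation (0.385, 0.14) no longer passed.

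With arrays scaled to the same spread, promoter counts were 13 for dmc1 and 1217 for sir2 as labelled. limma called 0 for pch2, sir2 turned, rDNA delete and translocation, with 281 to 512 at an unadjusted p under 0.05. Classical hotspot promoters of rDNA delete (0.16, 0.852) took the other sign. Calls ended for the right flank of sir2 as labelled (0.445, 0.102), rDNA delete (0.45, 0.347) and translocation (0.455, 0.232). Calls were added for the left flank of translocation against pch2 (-0.40, 0.0421).

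With centring on the 25th percentile, promoter counts were 2703 for dmc1, 524 for rDNA delete and 17 for translocation. limma then called 0 for pch2 and sir2 turned, with 623 to 669 at an unadjusted p under 0.05. A sign change was seen for CHA1 of dmc1 (0.18, 0.656), ORF interiors of dmc1 (0.47, 0.00377), centromeres of dmc1 (0.555, 0.000858), chromosome II of translocation (-0.145, 0.666) and chromosome XII of translocation (-0.090, 0.666). The sign turned for chromosome ends of dmc1 (0.46, 0.00414), convergent regions of dmc1 (0.48, 0.00366), the cassettes of dmc1 (0.48, 0.00366) and the left flank of dmc1 (0.25, 0.113) and sir2 turned (-0.070, 0.855). The left flank of rDNA delete (-0.090, 0.791) and the right flank of dmc1 (0.36, 0.0243) took the other sign. Lost calls were those of the left flank of orc1-161 (0.38, 0.187) and translocation (0.45, 0.111) and the right flank of sir2 as labelled (0.24, 0.388), rDNA delete (0.062, 0.791) and translocation (0.32, 0.234).

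Without the dye term, promoter counts were 4 for orc1-161 and 88 for translocation. Calls were lost for the left flank of translocation (0.52, 0.073) and the right flank of sir2 as labelled (0.35, 0.0853), rDNA delete (0.39, 0.118) and translocation (0.385, 0.13). With medians over probes, limma called 0 for translocation, with 960 at an unadjusted p under 0.05. Calls were lost for the right flank of rDNA delete (0.36, 0.0592). With the slide as a block, promoter counts were 1184 for dmc1, 8 for pch2, 6 for orc1-161, 543 for rDNA delete and 279 for translocation. The right flank of sir2 turned (0.37, 0.0453) newly passed.

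With bright probes alone, the promoter count was 2 for rDNA delete. Here limma called 0 for dmc1, pch2, orc1-161, sir2 as labelled, sir2 turned and translocation, with 0 to 10 at an unadjusted p under 0.05. A sign change was seen for GAT1 of dmc1 (-0.775, 0.572), chromosome II of translocation (-0.15, 0.907), divergent regions of dmc1 (-0.265, 0.567) and sir2 as labelled (0.20, 0.752) and the left flank of rDNA delete (-0.053, 0.931). The sign turned for the right flank of orc1-161 against pch2 (0.14, 0.945). The left flank of pch2 (0.47, 0.572), orc1-161 (0.43, 0.622), translocation (0.37, 0.926) and rDNA delete against pch2 (-0.525, 0.712) and the right flank of pch2 (0.83, 0.572) no longer passed. Calls ended for the right flank of orc1-161 (0.97, 0.531), sir2 as labelled (0.945, 0.191), rDNA delete (0.17, 0.931), translocation (0.64, 0.849) and rDNA delete against pch2 (-0.66, 0.712). Lost calls were those of the right flank of translocation against pch2 (-0.19, 0.916).

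Without rDNA delete replicate 2 and translocation replicate 1 together, the promoter count was 2 for rDNA delete. limma then called 0 for pch2, sir2 turned and translocation, with 545 to 868 at an unadjusted p under 0.05. The right flank of rDNA delete (0.475, 0.112) no longer passed. With promoters from 300 bp upstream, the promoter count was 1 for orc1-161. Here limma called 0 for pch2, sir2 turned and translocation, with 544 to 900 at an unadjusted p under 0.05. With promoters from 1000 bp upstream, the promoter count was 2 for pch2. limma called 0 for sir2 turned and translocation, with 662 to 1019 at an unadjusted p under 0.05.

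With flanks of 20 kb, the right flank of orc1-161 against pch2 (0.069, 0.883) took the other sign. Calls ended for the right flank of rDNA delete (0.18, 0.439) and translocation (0.40, 0.179). Calls were added for the left flank of rDNA delete (0.44, 0.0322) and translocation against pch2 (-0.63, 0.00279). With flanks of 30 kb, the left flank of translocation against pch2 (-0.46, 0.0109) newly passed. With flanks of 100 kb, lost calls were those of the right flank of rDNA delete (0.23, 0.225).

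With camera and an estimated correlation, calls were lost for the left flank of sir2 as labelled (1.09, p = 0.118) and rDNA delete against pch2 (-0.52, p = 0.0883) and the right flank of sir2 as labelled (0.60, p = 0.162), rDNA delete (0.21, p = 0.281) and translocation (0.40, p = 0.0763).

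In the authors' averages, which had no test, the left flank of sir2 changed sign against both directions, as labelled and turned (-0.018). Values moved for the left flank of pch2 (0.64), orc1-161 (0.53), translocation (0.46) and rDNA delete against pch2 (-0.37). The left flank of translocation against pch2 (-0.18) and the right flank of pch2 (0.98), orc1-161 (0.81), sir2 as labelled (0.11) and sir2 turned (0.11) moved. Values moved for the right flank of translocation (0.29) and rDNA delete against pch2 (-0.63). The table has 1 direction for sir2.

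With the replicate number as a block, promoter counts were 216 for dmc1, 6 for orc1-161, 4 for sir2 turned and 212 for rDNA delete, and limma called 0 for translocation, with 1079 at an unadjusted p under 0.05. The right flank of rDNA delete stood at 0.39 (adjusted p = 0.0612), and the block changed no other call of a flank or chromosome between strains. For dmc1 alone, of the lists that had passed, hotspot promoters still did, and both flanks (-0.36 left and -0.41 right), divergent regions and ORF interiors (adjusted p = 0.182 each), convergent regions and ends (0.221), cassettes (0.266) and centromeres (0.294) did not, nor did convergent regions of rDNA delete (0.0612). Deviations from group means of same-numbered arrays correlated at -0.22 to 0.47 over 15 group pairs, 7 over 0.1. With sir2 turned, all 10 pairs without dmc1 and none with it lay over 0.1. Among orc1-161, rDNA delete and translocation (shared scan days) r was 0.36, 0.47 and 0.21, and with pch2 (other days) 0.39, 0.36 and 0.33.

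When each array was left out in turn, the lone array of its group was assumed to vary like the other groups. Promoter counts ran from 340 to 793 for dmc1, 0 to 133 for pch2, 0 to 104 for orc1-161, 1089 to 1960 for sir2 as labelled, 0 to 166 for sir2 turned, 1 to 340 for rDNA delete, 0 to 131 for translocation, and, against pch2, from 0 to 12 for rDNA delete and 0 to 0 for orc1-161 and for translocation. Counts of 0 from limma came with 173 or more promoters at an unadjusted p under 0.05 for the comparisons with dmc1, and with all arrays limma's 0 against pch2 came with 70 for orc1-161, 396 for rDNA delete and 400 for translocation. Omission of dmc1 replicate 2 gave the highest counts for pch2, orc1-161, sir2 turned, rDNA delete and translocation, and omission of dmc1 replicate 1 gave 340 for dmc1 and 0 for pch2 and sir2 turned. The 1 for rDNA delete came without its replicate 2, the 12 against pch2 without its replicate 1, and the 1089 for sir2 as labelled without sir2 replicate 1.

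With arrays left out in turn, the left flank ran from 0.94 to 1.06 for pch2, 0.74 to 0.83 for orc1-161, 0.72 to 0.92 for sir2 as labelled, 0.12 to 0.32 for sir2 turned, 0.10 to 0.38 for rDNA delete and 0.62 to 0.71 for translocation. The right flank ran from 1.26 to 1.38 for pch2, 1.05 to 1.17 for orc1-161, 0.37 to 0.57 for sir2 as labelled, 0.24 to 0.45 for sir2 turned, 0.31 to 0.475 for rDNA delete and 0.385 to 0.78 for translocation. Against pch2 the left flank ran from -0.26 to -0.14 for orc1-161, -0.89 to -0.605 for rDNA delete and -0.38 to -0.26 for translocation, and the right from -0.26 to -0.16, -1.01 to -0.85 and -0.99 to -0.59. Chromosome II of the translocation ran from -0.029 (without dmc1 replicate 1) to 0.17 and chromosome XII from 0.060 to 0.19. The flank calls of pch2 and orc1-161 held in all 12 omissions. The right flank call of sir2 as labelled was lost without dmc1 replicate 1 (0.44) or sir2 replicate 1 (0.37), and sir2 turned passed there without sir2 replicate 1 (0.45). The right flank call of rDNA delete was lost without dmc1 replicate 1 (0.34) or 2 (0.45), either pch2 array (0.39), or rDNA delete replicate 1 (0.31) or 2 (0.475). The right flank call of translocation was lost without dmc1 replicate 1 (0.48) or translocation replicate 2 (0.385), and its left flank passed against pch2 without either sir2 array (-0.32).

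For 136 named gene results, 1374 of 1630 values kept sign and side of the threshold, 212 lost the call, 42 gained one and 2 changed sign. For 19 results of other lists the numbers were 133 of 213, 70, 0 and 10. With arrays left out, 1359 of 1632 gene values and 185 of 228 list values kept both, 264 and 43 lost the call, 9 and 0 gained one, and 0 changed sign.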

Other observations

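The regions, genes and arrays named in this part were chosen after their values were seen, and no explanation was tested for them.

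Beyond the rDNA, orc1-161 dmc1 lay above dmc1, relative to the array medians, in interior 50 kb stretches of several chromosomes. None of the tiles named in this paragraph passed with centring on the 25th percentile, an alternative chosen after seeing the data. Tiles rose on chromosome II (0.63 ± 0.16 at 400001 to 450000, adjusted p = 0.0181), on chromosome X (0.64 ± 0.15 at 350001 to 400000, 0.0147, and 0.52 at 400001 to 450000), and on chromosome XVI (0.54 and 0.56 at 400001 to 450000 and 450001 to 500000, 0.0385 each). Chromosomes XI (0.52), XIII (0.52) and XIV (0.535 and 0.55) each held further tiles that rose. Near the end of chromosome XII (1050001 to 1100000) the ratio rose in orc1-161 dmc1 (0.56 ± 0.15) and was lower in rDNA delete than in pch2 dmc1 (-0.62 ± 0.15, adjusted p = 0.0168).

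On the short chromosomes I and VI, mean enrichment at 5 h in pch2 dmc1 lay above the array median (0.49 ± 0.12, adjusted p = 0.00568, and 0.50 ± 0.11, 0.00485). In dmc1 it stood at 0.40 and 0.35 (0.111 each), and the difference of pch2 dmc1 from dmc1 did not pass (0.087 and 0.15, adjusted p = 0.772 and 0.537). Parts of both were lower than in pch2 dmc1 in rDNA delete (-0.66 at 150001 to 200000 of chromosome I and -0.74 at 200001 to 250000 of chromosome VI) and in the translocation (-0.75 and -0.68 at the same places), of which only that on chromosome VI in rDNA delete passed with centring on the 25th percentile (-0.70, 0.0481). The silent mating cassettes, which are cold for recombination, lay at -0.50 ± 0.092 in the translocation (adjusted p = 0.000123) and -0.38 ± 0.092 in pch2 dmc1 (0.00098). These chromosome and cassette means are relative to the array median, and no values with another centring are given. In rDNA delete 3 promoters were enriched at 5 h in limma's test against 0, those of ERG25, ERG11 and TIR3.

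Probes inside marker genes were bright in some strains. URA3 stood at 4.68 and 4.66 and LEU2 at 4.78 and 5.16 above the array median in the rDNA delete arrays, against 0.59 to 2.04 and 1.15 to 2.68 in the others. TRP1 stood at 1.86 and 1.73 in the arrays labelled sir2 dmc1, and at 1.00 or lower in the others. LYS2, which lies on chromosome II, stood at -0.51 and 0.034 in the translocation arrays, against 0.85 to 1.43 in the others.

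Several arrays correlated more closely with an array of another strain than with their own replicate. The second arrays of orc1-161 dmc1 and the translocation, which shared a scan day, a slide and the same dyes, correlated at r = 0.79. Those of rDNA delete and the translocation, scanned on the same day on different slides with opposite dyes, correlated at 0.62. Arrays scanned on different days reached similar values, with 0.72 between the second arrays of pch2 dmc1 and orc1-161 dmc1, 0.67 between those of pch2 dmc1 and the translocation, and 0.73 between the first arrays of pch2 dmc1 and rDNA delete. In each of these pairs both arrays had the same dyes, and no dye effect was removed from any of the correlations. The first arrays of the 3 strains that shared a day, all with the 5 h sample in Cy5, correlated at 0.56, 0.34 and 0.28. The last value is that of rDNA delete and the translocation, which shared a slide. Replicates correlated at 0.43 for orc1-161 dmc1, 0.22 for rDNA delete and 0.052 for the translocation.

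Mitochondrial probes stood at -1.73 and -1.49 in pch2 dmc1, 2.49 and 1.33 in the arrays labelled sir2 dmc1 as labelled and -2.49 and -1.33 after turning, -0.84 and -0.67 in orc1-161 dmc1, -0.81 and -0.86 in rDNA delete, and -0.55 and -0.74 in the translocation, the last 3 groups being those that shared 2 scan days.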
